A study of Drosophila melanogaster with 10 samples.

How the data were processed

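RNA was sequenced from wing imaginal discs (the larval epithelia that form the adult wing and notum) of the Drosophila melanogaster strain yw. Per the labels, discs were taken in the third larval instar at 6, 15, 25, 35 and 48 h after the molt from the second to the third instar, and the 48 h larvae were wandering. There were 10 libraries, 2 per time, named here by hour and replicate letter (15 h A is replicate A at 15 h). The labels give the molecule as polyA RNA, while the protocol they quote describes stranded libraries of total RNA depleted of ribosomal RNA. The labels do not say whether the replicates came from separate cultures, so every p-value measures only the spread between these libraries.

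According to the submitters' notes, reads were handled with STAR 2.7.10a and featureCounts, for which no version was given, with the builds dm6 and BDGP6. The strand setting of the counting, the normalization tool and any filter on genes were not stated. The unit of the deposited table is signal: gene read counts that the authors divided by 1 size factor per library. Multiplying each library by its own factor gave whole numbers within 0.001 reads for 100% of the values, and the factors lay within -0.572% and 0.705% of median-of-ratios factors recomputed from the recovered reads. Each of the 13041 genes of the table had at least 1 read in at least 1 library. The table covered 12668 of the 13986 protein-coding genes of the Ensembl BDGP6.54 annotation (dm6 assembly), from which all coordinates below were taken. For 233 genes the symbol came from the gene name table, 41 genes had no match in the annotation, and 46 shared a symbol with another gene. All 10 libraries of the table were used.

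The recovered reads per library ranged from 16814685 to 38003104, and 1 read equalled a signal of 0.596 to 1.40. Genes with a signal of at least 10 in at least 2 libraries were tested (10453), and 2588 were left out. The test was limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(signal + 1), 1 mean per time and 1 spread per gene shared over the 10 libraries (5 residual degrees of freedom, at least 6.90 in total after moderation), two-sided, with Benjamini-Hochberg adjustment over the 10453 genes of each comparison and a threshold of 0.05. All adjusted p-values of genes are from limma unless another tool is named. The comparisons were each time against the time before and 48 h against 6 h. A moderated F test covered all 5 times, and among its genes the time of the highest mean was recorded. A gene was counted as higher at a middle time when it passed the threshold against both 6 h and 48 h at 15, 25 or 35 h, and as lower likewise. Because 1 is added before the logarithm, fold changes of genes with low signal are understated. No fold is given against a time at which a gene had 0 or only 1 to 3 reads.

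Gene lists (31) were fixed: ecdysone response, temporal identity factors, wing axis patterning, proneural and sensory organ precursor genes, the E(spl) complex, the Hippo pathway, G1 to S phase, G2 to M phase, ribosome biogenesis, cytosolic ribosomal proteins, the respiratory chain, glycolysis, cuticle proteins, chitin synthesis and modification, zona pellucida proteins, basement membrane, JNK and damage, heat shock, antimicrobial peptides, Polycomb and Hox genes, replication-dependent histones, other RNAs without a poly(A) tail, male dosage compensation, adult muscle precursors, differentiated muscle, trachea, neurons, glia, haemocytes, fat body and salivary gland glue. For each list and comparison the members past the threshold were counted with the adjustment over all genes and adjusted over the list alone. Lists with at least 3 members tested were also compared with all other genes by camera, with a preset correlation between genes of 0.01 and again with an estimated correlation, and tested by fry; both were adjusted over all lists and comparisons. Of 140 camera tests, 63 passed with the preset correlation and 0 with the estimated one (lowest adjusted p 0.694). The estimate rests on differences between replicates, which were widest at 15 h. For G1 to S phase genes it was 0.928, with a median log2 difference of A from B of -0.61 at 15 h and -0.098 to 0.00051 at the other times. The estimate was not repeated without the 15 h pair, so how far that pair accounts for the lost calls is not known. The fry test does not compare a list with the other genes. At 48 h against 6 h its adjusted p for a shift in 1 direction was 0.00820 for wing axis and for ecdysone response genes, 0.00164 for proneural and 0.0318 for ribosome biogenesis genes. It was 0.0983 for the respiratory chain, 0.556 for temporal identity factors and 0.429 for fat body genes. Members that go both ways cancel in this form. The mixed form of fry, which counts changes either way, gave adjusted p 0.0434 for the respiratory chain, 1.68e-05 for temporal identity factors and 0.000207 for fat body genes. Families matched by symbol prefix can hold other genes: Cpr, a cytochrome P450 reductase, was among the cuticle proteins.

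Genes were named by a rule. Per comparison it took the 8 largest rises and the 8 largest falls among genes past the threshold whose libraries of one time all lay above or all below those of the other, with a mean of at least 50 at the higher time and a symbol that is not a bare annotation number. Per list and comparison it took up to 4 members past the threshold with the largest change. It also took a fixed set whether or not they passed: chinmo, br, Eip93F, Imp, Syp, lin-28, ab, EcR, Eip74EF, Eip75B, Hr3, Hr4, ftz-f1, wg, dpp, hh, vg, ap, ac, sc, ase, sens, Ilp8, Mmp1, puc, Antp, Ubx, twi, roX1 and roX2. For genes that peak or dip at a middle time it took the 5 largest each way. The genes mamo and Lim1 were outside the rule and are named only to complete the counts of their lists. For Ubx, twi, roX1 and roX2 no value was used here, and lin-28 and Hr3 were under the filter. The fixed lists, the naming rule, the tests of the report and every alternative below but the added one were chosen before the data were examined.

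Alternatives were a pseudocount of 0.5 or 5, no filter, a filter of at least 50, quantile normalization and a shift of each library to a common median, a fit of the 2 times compared alone, the replicate letter as a block, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. Leaving out 15 h A and 25 h A together was added after the data were seen, as were 6 lists, of which the report uses the trypsins and the closing section all, and some tests of the closing section, which it names. The tests were tested on simulated data with 200 changed genes among 10453. For 48 h against 6 h limma called 2% of genes changed 2-fold and 26% of genes changed 4-fold, and 6.67% of its calls were false. DESeq2 called 18% and 63%, and 37.2% of its calls were false. These shares depend on how many genes change. They need not hold for the data, where limma called 5130 genes at 48 h against 6 h.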

Results

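Gene expression was measured in wing imaginal discs at 5 times of the third larval instar, with n = 2 libraries at each of 6, 15, 25, 35 and 48 h after the molt from the second instar. The recovered reads of replicates A and B were 30993706 and 22198068 at 6 h, 28040176 and 24290363 at 15 h, and 23724569 and 25244372 at 25 h. At 35 h they were 16814685 and 17060414, and at 48 h 33846755 and 38003104. Between 10865 and 12294 genes had a read in a library. Genes of the mitochondrial genome took 3.71% to 6.48% of the reads, ribosomal RNA genes 4.79% to 13.0%, and the 10 most abundant genes of a library 9.76% to 28.5%. Values below are mean signal ± SD over the n = 2 libraries of a time, and changes are on the log2(signal + 1) scale with the standard error (SE) of the limma fit. Some genes overlap others or have close paralogs; since the strand setting of the counting is not known, their values can include reads of a neighbour.

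Replicates of one time correlated across the 10453 genes tested with a Spearman coefficient of 0.976 at 6 h, 0.979 at 25 h, 0.993 at 35 h and 0.994 at 48 h, but 0.870 at 15 h; genes are not independent replicates. Between 15 h A and 15 h B, 2754 genes differed more than 2-fold, 2296 of them higher in A, against 742 to 1473 genes at the other times. The SD of the log2 difference between replicates was 1.66 at 15 h and 0.537 to 0.872 at the other times. Since limma shares 1 spread per gene over all times, this gap enters every comparison, also those without 15 h. Leaving out either 15 h A or 15 h B removes it and does not alter the size of changes between other times. Trypsin genes, which encode digestive enzymes of the gut, took 0.994% of the reads of 15 h A and 0.0156% of those of 15 h B. Genes of the fat body list took 15.8% and 8.74% of the reads at 25 h A and B and between 0.208% and 1.80% in the other libraries.

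**Figure D1:**
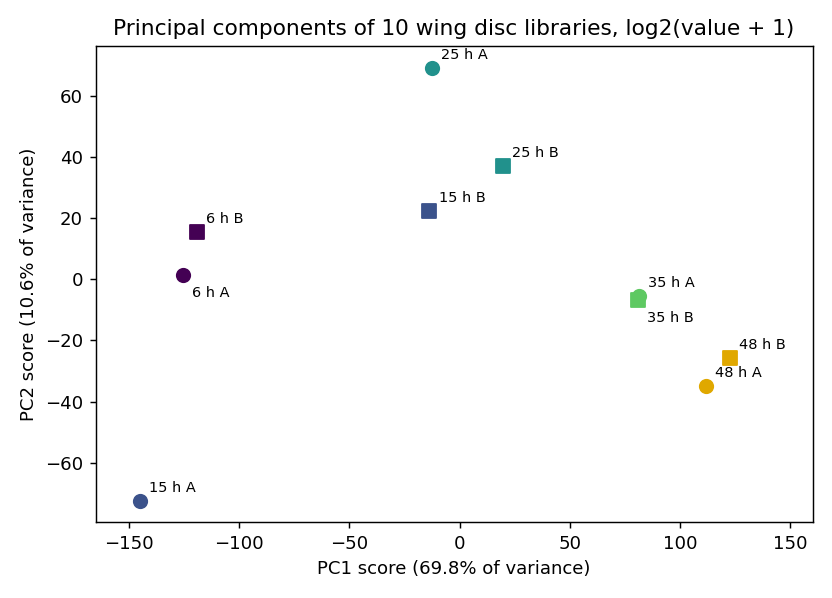
Principal components of the 10453 tested genes on the log2(signal + 1) scale, 1 point per library, coloured by time, with the share of variance on each axis (69.75% on the first and 10.64% on the second). The libraries follow their time along the first component except 15 h A, which lies at -144.9, beyond 6 h A (-125.5) and 6 h B (-119.1), while 15 h B lies at -13.7.

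The comparison of 48 h with 6 h asks which genes differed between the wandering stage and the start of the instar. Among the factors that mark early and late developmental age, chinmo and Imp fell while br and Syp rose. chinmo (FBgn0086758, 2L 1651258 to 1704682, plus strand), a zinc finger factor of early larval identity, fell from 9667 ± 223 to 1231 ± 46.7, a log2 change of -2.97 (SE 0.19, adjusted p 0.000219). Imp (FBgn0285926), an RNA-binding protein of young neuroblasts, fell from 5547 ± 1206 to 2148 ± 30.8 (log2 -1.35, adjusted p 0.00224). br (FBgn0283451, X 1575132 to 1664869, plus strand), which encodes the Broad factors of the late larva and prepupa, rose from 3766 ± 743 to 23246 ± 1545 (log2 2.64, SE 0.21, adjusted p 0.000357). Syp (FBgn0038826), an RNA-binding protein of old neuroblasts, rose from 8696 ± 2125 to 38214 ± 57.2 (log2 2.16, adjusted p 0.000323). Mean chinmo signal at 6, 15, 25, 35 and 48 h was 9667, 9884, 7284, 4883 and 1231, and that of br was 3766, 6890, 11569.8, 17757 and 23246. Of 7 temporal identity factors tested, 2 were higher and 3 lower (2 and 3 adjusted over the list alone; camera adjusted p 0.734), the third lower one being mamo (log2 -1.27). ab, a zinc finger factor, and Eip93F, which specifies late fates, did not pass (log2 -0.51 and 0.69, adjusted p 0.0927 and 0.448); without 15 h A the fall of ab passed at 0.00141.

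**Figure D2:**
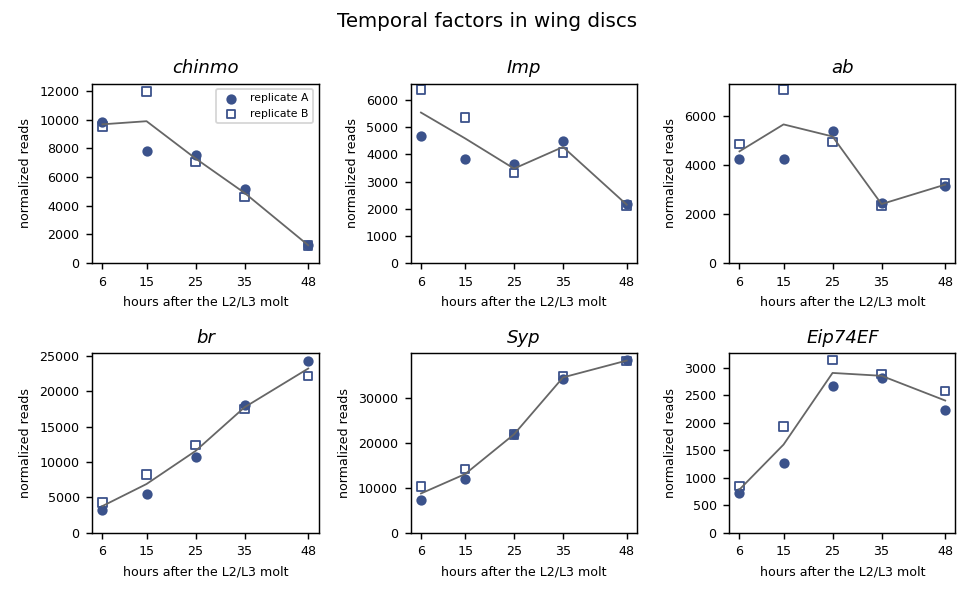
Signal of chinmo, Imp, ab, br, Syp and Eip74EF (vertical axes) against hours after the molt, with filled circles for replicate A, open squares for replicate B and a line through the means. Mean chinmo signal is 9667 at 6 h and 1231 at 48 h, while mean br signal is 3766 and 23246.

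Most ecdysone response genes were higher at 48 h. ImpE2 (FBgn0001254, 3L 3510974 to 3512681, minus strand), an ecdysone-inducible gene of everting discs, went from 20.5 ± 2.53 to 64052 ± 20150, the largest rise among the genes the naming rule admits (log2 11.51, SE 0.82, adjusted p 0.000267). ImpE1 (FBgn0001253), of the same class, rose by 5.73 (adjusted p 0.000418), Eip78C, a nuclear receptor, by 3.91, and ImpE3 by 4.91 on the log2 scale. Blimp-1 (FBgn0035625), an ecdysone-induced repressor, rose from 13.6 ± 7.16 to 2073 ± 1982 (log2 6.80, SE 1.19, adjusted p 0.00465). Eip74EF, an ETS factor, rose by 1.62 and Eip75B, a nuclear receptor, by 0.98. The receptor gene EcR rose by 0.73 (adjusted p 0.0104), but not past the threshold without 6 h A (0.0589) or 48 h B (0.0718). The nuclear receptor gene Hr4 rose by 3.82 (adjusted p 0.0146), but not past it without 6 h A (0.0746) or 6 h B (0.0529). ftz-f1 (FBgn0001078), a nuclear receptor of the mid-prepupa, fell from 1437 ± 30.5 to 535 ± 87.5 (log2 -1.43, adjusted p 0.000671). Hr38, a nuclear receptor that pairs with the ecdysone co-receptor, fell from 286 ± 128 to 3.16 ± 0.257 (log2 -6.03). Of 24 ecdysone response genes tested, 15 were higher and 4 lower (15 and 5 adjusted over the list alone). For this list camera gave an adjusted p of 0.00207, and 0.694 with an estimated correlation. Small heat shock genes that lie side by side on 3L rose as well: Hsp23 (FBgn0001224, 3L 9381882 to 9382765) from 263 ± 56.8 to 66842 ± 2768 (log2 8.0, adjusted p 0.000961), Hsp67Ba by 7.39 and Hsp27 by 5.28. For the heat shock list 4 of 10 were higher and 1 lower (4 and 1 adjusted over the list alone). The median of that list was -0.33, its mean 1.82, and camera pointed up (adjusted p 0.267); under quantile normalization the median was 0.99.

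Most wing axis genes and some sensory organ genes rose over the same span. Doc2 (FBgn0035956, 3L 9012686 to 9019246, minus strand), a T-box factor of the hinge and notum, rose from 41.2 ± 13.5 to 875 ± 19.2 (log2 4.41, adjusted p 0.000201). Dll, a homeobox gene of the wing margin, rose by 3.63, and ara, an Iroquois gene of the notum, by 2.68. The compartment and margin genes hh, vg and wg, which encode the ligand Hedgehog, the wing selector Vestigial and the ligand Wingless, rose by 1.62, 1.56 and 0.80 (adjusted p 0.000961, 0.00345 and 0.00434). ap, the dorsal selector, rose by 0.88 (adjusted p 0.0146), but not past the threshold without 6 h A, 6 h B, 48 h A or 48 h B (0.0635, 0.0666, 0.0584 and 0.0817). The ligand gene dpp did not pass (log2 0.09, adjusted p 0.766), nor did the Hox gene Antp (-0.43, 0.0624), which passed at 0.0108 without 15 h A. Of 37 wing axis genes, 32 were higher and 1, the LIM homeobox gene Lim1, was lower (32 and 1 adjusted over the list alone). The median change of these genes was 1.20, with a camera adjusted p of 6.23e-11, and 0.710 with an estimated correlation. The proneural gene sc (FBgn0004170) rose from 54.9 ± 11.05 to 761 ± 70.9 (log2 3.78, adjusted p 0.000201), its neighbour ac by 3.65, and sca, a secreted protein of proneural clusters, by 3.52. sens (FBgn0002573, 3L 13396228 to 13401125, minus strand), a zinc finger factor of sensory organ precursors and margin cells, rose from 8.28 ± 0.393 to 203 ± 11.2 (log2 4.46, adjusted p 0.00022). ase, a neural precursor gene, did not pass (log2 1.78, adjusted p 0.250). In the proneural list 7 of 15 were higher and 2 lower (8 and 2 adjusted over the list alone; camera 0.0153, and 0.694 with an estimated correlation).

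**Figure D3:**
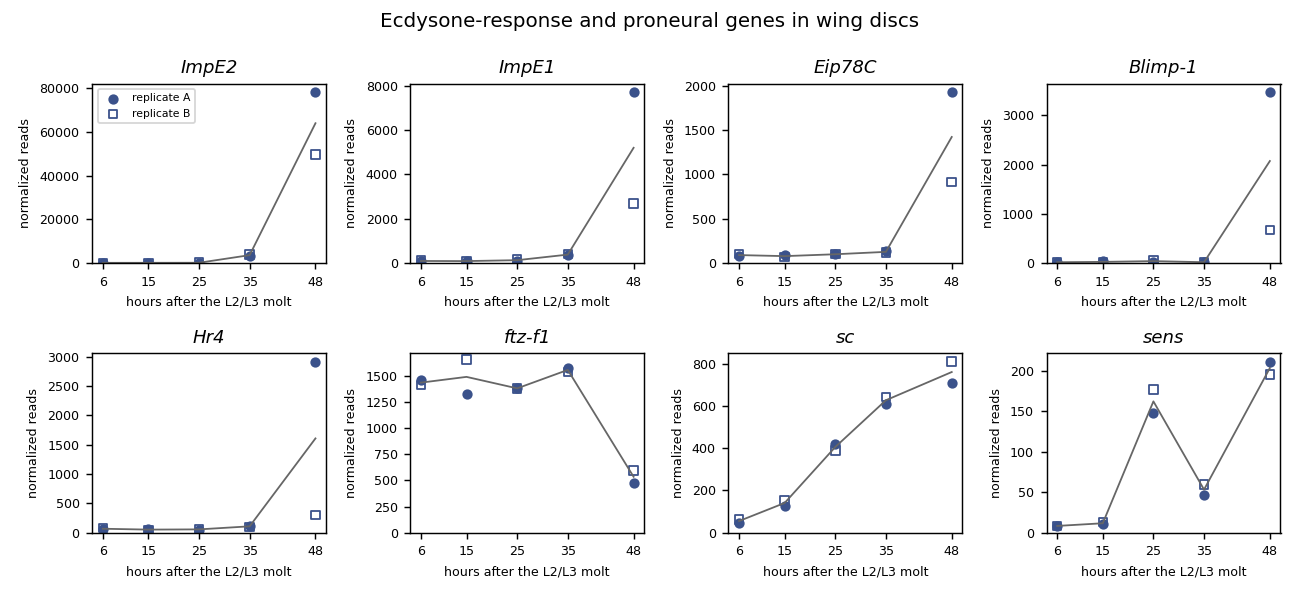
Signal of ImpE2, ImpE1, Eip78C, Blimp-1, Hr4, ftz-f1, sc and sens (vertical axes) against hours after the molt, with filled circles for replicate A, open squares for replicate B and a line through the means. Mean sens signal is 11.6 at 15 h, 162 at 25 h, 53.2 at 35 h and 203 at 48 h.

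Notch targets of the E(spl) complex were higher for 7 of 12 members and lower for 2 (8 and 2 adjusted over the list alone; camera adjusted p 0.0127, and 0.736 with an estimated correlation). E(spl)m6-BFM and E(spl)malpha-BFM, members of the Bearded family, rose by 3.80 and 3.36, and E(spl)m7-HLH, a basic helix-loop-helix repressor, by 2.53. Kaz-m1, a protease inhibitor gene that lies in the complex, fell by 5.67 (adjusted p 0.0341), a call lost without any 1 library of 6, 25, 35 or 48 h (adjusted p 0.0552 to 0.131). In the Hippo list 12 of 16 were higher and 1 lower (14 and 1 adjusted over the list alone; camera 0.000600, and 0.713 with an estimated correlation). Among them were the atypical cadherin gene ds (1.17), the growth coactivator gene yki (0.84) and its upstream gene mats (0.82). Some Polycomb group genes rose, with ph-p at 1.32, Su(z)2 at 1.15 and ph-d at 1.13. In all, 13 of the 20 Polycomb and Hox genes were higher and 1 lower, the head Hox gene Dfd (13 and 3 adjusted over the list alone; camera 0.00924, and 0.736 with an estimated correlation). The call of Dfd was lost without 6 h A, 6 h B or 48 h A (adjusted p 0.0774, 0.0859 and 0.115). Zona pellucida genes of the apical matrix were higher for 7 of 11 and lower for 1 (7 and 1 adjusted over the list alone; camera 0.0111, and 0.713 with an estimated correlation). Among them were nyo at 5.32, dy at 4.55, neo at 3.50 and mey at 2.54. Of 9 tracheal genes, 4 were higher and 2 lower (4 and 2 adjusted over the list alone; median 0.13, mean -0.06, camera up at 0.435); dysf and vvl, transcription factors also active outside the trachea, rose by 2.28 and 2.01. Of 4 adult muscle precursor genes, 2 were higher (2 adjusted over the list alone; camera 0.125), the cell adhesion gene hbs (2.75) and the immunoglobulin gene Ama (1.11). Ama was not past the threshold without any 1 library of 6 or 48 h (adjusted p 0.0517 to 0.0742).

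Of 27 G1 to S phase genes, 2 were higher and 1 lower (2 higher adjusted over the list alone; camera 0.658), the kinase gene Cdk4 (0.88) and the factor gene E2f1 (0.45) being higher. Of 28 G2 to M phase genes 4 were higher, and 0 adjusted over the list alone; their median was 0.43 (camera 0.00667, and 0.823 with an estimated correlation). The mitotic genes pim and CycB rose by 1.03 and 0.72. These calls were lost without any 1 library of 6 or 48 h, and that of CycB also without 1 of 35 h (adjusted p 0.0515 to 0.140). Without 15 h A, 23 of the 28 passed as higher.

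Genes of ribosome synthesis fell. mod (FBgn0002780), a nucleolar protein, fell from 37109.6 ± 260 to 15402 ± 187 (log2 -1.27, SE 0.15, adjusted p 0.00101), and nclb, Surf6 and Nop56, all of ribosome assembly, changed by -1.36, -1.20 and -1.16. Of 24 ribosome biogenesis genes, 21 were lower (1 higher and 21 lower adjusted over the list alone; median -0.93, camera 3.00e-05, and 0.736 with an estimated correlation). Of 88 cytosolic ribosomal protein genes 24 were lower, and 1 adjusted over the list alone (camera 9.92e-05, and 0.775 with an estimated correlation). Their median of -0.21 turned to 0.17 under quantile normalization and 0.11 with a common median, so that no direction holds for this list. RpLP0-like (log2 -1.03) is an assembly factor of that family and not a ribosomal protein. Nuclear genes of the respiratory chain were lower for 52 of 71 (56 adjusted over the list alone; median -1.31, camera 5.04e-07, and 0.754 with an estimated correlation). UQCR-C2 of complex III and COX5B of complex IV changed by -1.87 and -1.76, calls lost without any 1 library of 6 h or 48 h (adjusted p 0.0622 to 0.0756). Glycolysis genes were lower for 9 of 11 (9 adjusted over the list alone; median -1.45, camera 0.000616, and 0.710 with an estimated correlation). The hexokinase gene Hex-C was at -4.50, the lactate dehydrogenase gene Ldh at -3.85 and the aldolase gene Ald1 at -2.59. Genes of muscle and of the gut fell over the same span. Relative to its mean over the 10 libraries, the differentiated muscle list stood at 1.70 and 2.13 on the log2 scale at 6 h A and B and at -3.04 and -3.53 at 48 h A and B. The trypsin list stood at 3.65 and 3.50 and then at -3.64 and -3.25.

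The largest falls under the naming rule included genes of larval cuticle, matrix and gut enzymes. Lcp65Ag2 (FBgn0020638, 3L 6134697 to 6135274, minus strand), a larval cuticle protein, fell from 27176 ± 6216 to 5.76 ± 2.25 (log2 -11.99, SE 0.52, adjusted p 0.000122). prc, a matrix protein, fell from 11922 ± 5196 to 6.62 ± 0.0929 (log2 -10.54). The gut protease genes epsilonTry and Jon99Fii fell from 43563 ± 45525 and 12665 ± 11238 to 22.1 ± 1.80 and 10.7 ± 8.49 (log2 -10.31 and -9.94); epsilonTry was not past the threshold without 6 h A (adjusted p 0.0535). GstD7, a glutathione transferase gene, and CAH9, a carbonic anhydrase gene, had 5108 ± 194 and 4392 ± 1008 at 6 h and 2.94 ± 2.47 each at 48 h. The lipid-binding gene Acbp4 and Pgcl had 1381 ± 298 and 3025 ± 3824 at 6 h and 0.334 ± 0.473 each at 48 h. Among 8 cuticle genes 4 were lower and 1 higher (4 and 1 adjusted over the list alone; camera 0.0611), and among 23 chitin genes 13 were lower and 6 higher (13 and 6 adjusted over the list alone; camera 0.167). The chitinase-like growth factor genes Idgf5, Idgf2 and Idgf1 changed by -5.72, -4.70 and -4.29. Of 17 basement membrane genes 9 were lower and 2 higher (9 and 2 adjusted over the list alone; camera 0.0712); the collagen IV genes Col4a1 and vkg, which fat body and blood cells also express, changed by -3.95 and -3.83. Of 11 haemocyte genes 9 were lower (9 adjusted over the list alone; median -2.37, camera 0.000616, and 0.694 with an estimated correlation), with the secreted peptide gene Nplp2 at -7.75 and the prophenoloxidase genes PPO1 and PPO2 at -3.58 and -3.51. All 4 differentiated muscle genes tested were lower (4 adjusted over the list alone; median -5.20, camera 0.00211, and 0.694 with an estimated correlation). Act57B, a muscle actin, fell from 154251 ± 36580 to 3962 ± 914. The other genes of that list were not analysed here.

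The remaining lists gave mixed or small counts at 48 h against 6 h. Fat body genes went both ways, 3 of 9 higher and 2 lower (3 and 2 adjusted over the list alone; camera 0.770). The storage protein gene Lsp2 rose by 4.43 and the storage protein receptor gene Fbp1 by 6.04, while the lipoprotein genes apolpp and Apoltp changed by -5.87 and -8.04. Salivary gland glue genes were higher for 7 of 10 and lower for 2 (7 and 2 adjusted over the list alone; camera 0.112). Neuronal genes were lower for 5 of 10 (5 adjusted over the list alone; camera 0.0736), the channel gene para going from 72.1 ± 39.7 to 2.86 ± 0.678. Glial genes were lower for 3 of 7 (1 higher and 3 lower adjusted over the list alone; camera 0.390), with moody, a receptor of the blood-brain barrier, at -1.64. JNK and damage genes were higher for 3 of 19 and lower for 5 (3 and 5 adjusted over the list alone; camera 0.560). The median of this list, -0.23, turned to 0.14 under quantile normalization and 0.09 with a common median. The cytokine genes upd3 and upd1 changed by -2.47 and -1.82. The JNK targets puc and Mmp1 and the growth delay hormone gene Ilp8 did not pass (adjusted p 0.303, 0.804 and 0.0528), but Ilp8 passed at 0.00801 without 15 h A. Antimicrobial peptide genes were lower for 2 of 8, and 0 adjusted over the list alone (camera 0.139); of these Dro had 40.01 ± 22.7 at 6 h and 0 at 48 h, a call lost without 35 h A or any 1 library of 6 or 48 h (adjusted p 0.0501 to 0.128). The 2 replication-dependent histone genes and the 1 dosage compensation gene tested did not pass, and no gene of the other RNAs without a poly(A) tail was analysed here.

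**Figure D4:**
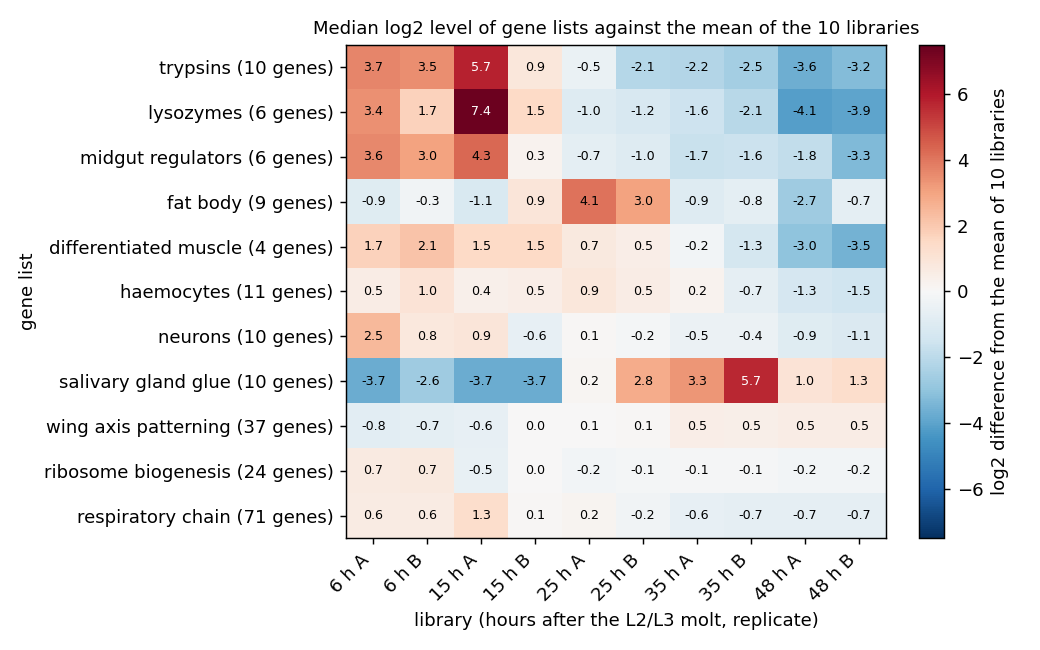
Heat map of 11 gene lists (vertical axis) over the 10 libraries (horizontal axis); colour gives the median log2 signal of a list relative to its mean over the 10 libraries. The trypsin list stands at 5.75 in 15 h A and 0.88 in 15 h B, and the muscle list falls from 1.70 and 2.13 at 6 h to -3.04 and -3.53 at 48 h.

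At 48 h against 6 h, 2332 genes were higher and 2798 lower in limma (772 and 2161 of them at least 2-fold). In all 5130 the libraries of the 2 times did not overlap. Genes chosen by the test on these same libraries are nearly bound to be apart, so this adds no support. Chance alone separates 33.3% of genes not chosen by a test at n = 2 against 2. Of 125 named calls, 94 passed in each of the 10 fits with 1 library left out and 31 were lost in at least 1. The counts were lowest without 48 h B (1115 and 1384) and highest without 15 h A (3214 and 3955, with all 5130 calls kept). They moved over 1.5 times also without 6 h A (1359 and 1636), 6 h B (1364 and 1603) and 48 h A (1194 and 1496). The change of a gene shifted by a median of 0.45 under quantile normalization and 0.32 with a common median. As deposited 45.5% of the calls were rises, against 66.5% after quantile normalization and 58.8% with a common median, and changes smaller than these shifts depend on the scaling.

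The comparison of 15 h with 6 h asks what changed early in the instar. Poxn (FBgn0003130), a paired-box gene of chemosensory organs and the hinge, rose from 12.1 ± 3.72 to 99.99 ± 19.7 (log2 2.97, SE 0.27, adjusted p 0.0194), and Doc2 from 41.2 ± 13.5 to 241 ± 27.7 (log2 2.55, adjusted p 0.0194). Some proneural genes were already rising, with ac, sc and sca up by 1.36, 1.35 and 1.01 (adjusted p 0.0414, 0.0239 and 0.0267), while the RNA-binding protein gene cpo fell by 1.08. Nucleolar genes dropped to about their later level, mod from 37109.6 ± 260 to 15685 ± 3649 (log2 -1.26, adjusted p 0.0194) and Nop56 by 1.25. Eip74EF rose from 785 ± 95.6 to 1604 ± 463 (log2 1.0, adjusted p 0.0460). The fat body genes Lsp2 and Fbp2, a storage protein and an alcohol dehydrogenase relative, rose from 60.4 ± 46.7 and 253 ± 92.9 to 1671 ± 717 and 7231 ± 6889 (log2 4.94 and 4.44). The lipoprotein gene Apoltp fell by 3.10. Osi14, of a family of cuticle-linked membrane proteins, rose by 2.39, as did the zona pellucida gene nyo, and Hsp27 by 2.14. The larval gene Lcp65Ag2 fell by 2.61 (adjusted p 0.0444) and the peptidase gene Ance-4 by 3.49. The mucin gene Muc26B and the immune peptide gene IM14 had 69.9 ± 37.1 and 65.6 ± 72.0 at 6 h and 0 at 15 h, while BomS1, another immune peptide gene, went from 530 ± 652 to 3.33 ± 2.89.

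Of the lists at 15 h against 6 h, wing axis genes were higher for 6 of 37 (9 adjusted over the list alone; camera adjusted p 3.88e-07, and 0.713 with an estimated correlation). Relative to its mean over the 10 libraries, this list stood at -0.81 and -0.72 on the log2 scale at 6 h A and B. It stood at -0.60 in 15 h A and 0.05 in 15 h B, so most of the rise was in 15 h B. Proneural genes were higher for 3 and lower for 1 of 15 (3 and 1 adjusted over the list alone). Ribosome biogenesis genes were lower for 16 of 24 (21 adjusted over the list alone; median -1.02, camera 2.00e-16, and 0.694 with an estimated correlation). Ecdysone response genes were higher for 2 of 24 (5 adjusted over the list alone), zona pellucida genes for 3 of 11 (4 adjusted over the list alone; camera 0.00236, and 0.694 with an estimated correlation). The 2 lower genes of the ribosomal protein list (1 adjusted over the list alone), RpLP0-like and RpL24-like, encode assembly factors. BomS1, Lsp2, Fbp2 and Apoltp are fat body genes, and the fat body list took 0.974% and 1.79% of the reads at 6 h A and B and 0.308% and 1.80% at 15 h A and B. In limma 138 genes were higher and 303 lower, 441 calls in all (1128 and 1264 at an unadjusted p under 0.05). After quantile normalization 9 were higher and 14 lower, with 22 of the 441 calls shared. With a common median 4 were higher and 5 lower, with 9 shared. Without 15 h A the counts were 1970 and 1848, including all 441. EcR, br, Syp, vg and hh then passed with rises of 0.96, 1.15, 0.72, 0.88 and 0.67; without 15 h B the values were 0.45, 0.57, 0.47, -0.01 and 0.05, and only EcR of these 5 passed (adjusted p 0.0139). chinmo passed with a rise of 0.31 without 15 h A (adjusted p 0.0346) and with a change of -0.31 without 15 h B (0.0412), and did not pass with all 10 libraries (adjusted p 1), so no direction holds for it here. Without 15 h B the counts were 1975 and 1005. No gene passed without any 1 library of 6, 35 or 48 h (limma; 617 to 889 higher and 833 to 1121 lower at an unadjusted p under 0.05). A set of 24 higher with 95 or 97 lower passed without 25 h A or B. On all 10 libraries edgeR called 0 and DESeq2 666 higher and 715 lower.

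The comparison of 25 h with 15 h asks what changed in the middle of the instar. sens rose from 11.6 ± 1.85 to 162 ± 20.9 (log2 3.70, SE 0.28, adjusted p 0.0202) and sca from 371 ± 72.6 to 1083 ± 73.8 (log2 1.55, adjusted p 0.0263). sc, at 141 ± 17.1 and 406 ± 22.02, did not pass (log2 1.53, adjusted p 0.0611). sage (FBgn0037672, 3R 9262654 to 9264142, minus strand), a basic helix-loop-helix gene of the salivary gland, rose from 41.7 ± 2.76 to 584 ± 7.98 (log2 3.78, SE 0.24, adjusted p 0.0108). The salivary gland glue list went from a level of -3.72 and -3.73 at 15 h A and B to 0.16 and 2.77 at 25 h A and B, relative to its mean over the libraries. Of its 10 genes 0 passed over all genes and 7 were higher adjusted over the list alone (camera 1.45e-05, and 0.694 with an estimated correlation). Hsp67Ba, a small heat shock gene, rose by 3.39. Alp1, an alkaline phosphatase gene, NimC2, a receptor gene of blood cells, and Tsp42Ep, a tetraspanin gene, rose from 12.0 ± 4.82, 8.79 ± 0.277 and 21.9 ± 3.57 to 612 ± 464, 295 ± 115.3 and 343 ± 86.2. These 3 calls were lost without 15 h A (adjusted p 0.0595, 0.0687 and 0.0687). The 1 lower gene, CG14302, was outside the naming rule and is named after its values were seen: it went from 218 to 25.4 (log2 -3.06, adjusted p 0.0255).

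At 25 h against 15 h, 13 genes were higher and 1 lower in limma (750 and 798 at an unadjusted p under 0.05), edgeR gave 2 and 1 and DESeq2 383 and 785. Without 15 h B, limma gave 2185 and 2721, and without 15 h A 6 and 1 with 4 of the 14 calls shared. None passed without 25 h A, 48 h A or 48 h B (limma; 481 to 614 higher and 437 to 565 lower at an unadjusted p under 0.05). Between 2 and 5 genes were higher and 0 or 1 lower without 6 h A, 6 h B, 25 h B, 35 h A or 35 h B. Of the lists, proneural genes were higher for 2 of 15 (4 adjusted over the list alone; camera 0.0227, and 0.694 with an estimated correlation) and heat shock genes for 1 of 10 (1 adjusted over the list alone). Fat body genes, with a median change of 4.13, had 9 of 9 higher adjusted over the list alone but 0 over all genes (camera 2.56e-08, and 0.694 with an estimated correlation). Their share of the reads went from 0.308% and 1.80% to 15.8% and 8.74%. The change of a gene shifted by a median of 0.15 under quantile normalization and 0.13 with a common median.

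The comparison of 35 h with 25 h covers the approach to wandering. ImpE2 rose from 60.3 ± 59.5 to 3552 ± 564 (log2 6.31, SE 0.82, adjusted p 0.0235), and the homeobox gene hth of the hinge by 0.77 (adjusted p 0.0368). ab (FBgn0264442) fell from 5179 ± 308 to 2409 ± 79.7 (log2 -1.10, adjusted p 0.0455). sens fell from 162 ± 20.9 to 53.2 ± 8.74 (log2 -1.59, SE 0.28, adjusted p 0.0360), and kibra, an upstream Hippo gene, from 863 ± 4.59 to 389 ± 0.233 (log2 -1.15, adjusted p 0.0245). PPO3, a prophenoloxidase gene of lamellocytes, rose from 78.1 ± 5.18 to 527 ± 82.9 (log2 2.73, SE 0.22, adjusted p 0.0177). ItgaPS4, an integrin gene, rose from 17.0 ± 2.25 to 533 ± 206 (log2 4.84) and alphaTub85E, a tubulin gene, from 113 ± 42.7 to 1208 ± 374 (log2 3.42). chinmo (7284 to 4883, log2 -0.58) and br (11569.8 to 17757, log2 0.62) did not pass (adjusted p 0.143 and 0.163). Both passed without 15 h A, a fit that leaves 1 library at 15 h. Genes of the fat body were among the falls. The storage protein genes Lsp1alpha and Lsp1gamma fell from 729897 ± 200767 and 1223710 ± 852047 to 15841 ± 3511 and 25253 ± 7989 (log2 -5.52 and -5.44, adjusted p 0.0408 each). The clotting protein gene fon changed by -5.44 and apolpp by -5.36. GstD3, a glutathione transferase gene with close paralogs, went from 4152 ± 224 to 96.8 ± 131 (log2 -7.07, adjusted p 0.0473), and was at 2730 ± 499 again at 48 h. It had 4.03 in 35 h A and 190 in 35 h B. With 1 library left out its change ranged from -9.69 to -4.44 and its adjusted p up to 0.226, with the call kept in 4 of 10 fits.

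At 35 h against 25 h, fat body genes were lower for 6 of 9 (8 adjusted over the list alone; median -4.98, camera 4.68e-07, and 0.694 with an estimated correlation). Glycolysis genes were lower for 6 of 11 (8 adjusted over the list alone; camera 1.35e-07, and 0.694 with an estimated correlation), with the trehalose transporter gene Tret1-1 at -2.63. Chitin genes were lower for 6 of 23 (10 adjusted over the list alone; camera 0.00591, and 0.694 with an estimated correlation), among them Idgf5 (-5.27) and Idgf3 (-2.97). Basement membrane genes were lower for 2 of 17 (1 higher and 5 lower adjusted over the list alone; camera 0.00924, and 0.713 with an estimated correlation): trol, the perlecan gene, fell from 46233 ± 4767 to 11274 ± 699. Ribosomal protein genes were lower for 11 and higher for 2 of 88 (37 and 4 adjusted over the list alone; camera 1.49e-11, and 0.713 with an estimated correlation). The median of that list, -0.24, turned to 0.09 under quantile normalization. Its member RpL23A fell by 1.07. The wing axis list had 1 of 37 higher (1 adjusted over the list alone; camera 2.03e-07, and 0.713 with an estimated correlation). In limma 89 genes were higher and 323 lower. Without 15 h A the counts were 1042 and 1437 and without 15 h B 1015 and 1420, including all 412 calls. None passed without 48 h A or B (limma; 620 higher and 1094 or 1097 lower at an unadjusted p under 0.05; edgeR 21 and 130, DESeq2 406 and 840 on all libraries). The counts were 0 higher and 1 or 2 lower without 25 h A, 35 h A or 35 h B. They were 5 and 52 without 6 h A, 3 and 34 without 6 h B, and 40 and 347 without 25 h B. Here the median shift of a gene was 0.21 under quantile normalization and 0.18 with a common median.

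The comparison of 48 h with 35 h covers the onset of wandering. chinmo fell from 4883 ± 406 to 1231 ± 46.7 (log2 -1.98, SE 0.19, adjusted p 0.0229), and ftz-f1 from 1559 ± 28.9 to 535 ± 87.5 (log2 -1.55, SE 0.15, adjusted p 0.0229). Among the ecdysone genes, ImpE1 went from 375 ± 26.7 to 5207 ± 3563 (log2 3.60, adjusted p 0.0491), Eip78C from 125 ± 13.7 to 1422 ± 720 (log2 3.41, adjusted p 0.0289). ImpE3 rose by 2.93 and Eip75B by 1.04 (adjusted p 0.0424 and 0.0497), while Hr38 fell by 3.37. Spn100A (FBgn0039795), a serine protease inhibitor gene, rose from 7.90 ± 0.222 to 2156 ± 1876 (log2 7.58, SE 0.72, adjusted p 0.0229), and Spn43Aa, another one, from 213 ± 36.8 to 1938 ± 421 (log2 3.18). wbl, a gene of dorsoventral patterning in the egg, and mthl3, a receptor gene, rose by 2.21 and 1.81, and Vajk4, a cuticle gene, went from 1.99 ± 0.986 to 103 ± 45.8. The muscle actin gene Act57B fell by 2.7 (adjusted p 0.0494), beside a haemocyte list with a median change of -1.14. The lysosomal mannosidase genes LManVI and LManIII changed by -4.71 and -4.68. alphaTub85E fell by 4.18, back to 67.2 ± 28.8. A 28S ribosomal RNA pseudogene, 28SrRNA-Psi:CR45860, was at 2128 ± 1507, 20386 ± 2718 and 380 ± 51.0 at 25, 35 and 48 h; its reads can come from ribosomal RNA left in the libraries. sens (log2 1.92, adjusted p 0.0512), Imp (-0.99, 0.0878), Blimp-1 (6.76, 0.0739) and Hr4 (3.12, 0.220) did not pass; without 15 h A sens passed at 0.0134 and Imp at 0.0149.

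At 48 h against 35 h, ecdysone response genes were higher for 4 and lower for 2 of 24 (9 and 3 adjusted over the list alone; camera 0.00177, and 0.694 with an estimated correlation). Temporal identity factors had 1 of 7 lower (2 adjusted over the list alone). The differentiated muscle list had 1 of 4 lower (4 adjusted over the list alone; camera 4.30e-07, and 0.694 with an estimated correlation). Ribosomal protein genes were higher for 1 of 88 (21 higher and 3 lower adjusted over the list alone; camera 1.72e-12, and 0.713 with an estimated correlation). In limma 16 genes were higher and 25 lower, 41 calls in all (568 and 682 at an unadjusted p under 0.05). These counts were 0 and 1 after quantile normalization and 8 and 13 with a common median. They were 0 and 2 with the block and 624 and 496 in the 2 times alone. Without 15 h A the counts were 492 and 553 and without 15 h B 481 and 541, including all 41 calls. With any other library left out they were at most 5 higher and 13 lower. None passed without 48 h A (limma; 253 and 397 at an unadjusted p under 0.05; edgeR 5 and 5, DESeq2 247 and 322 on all libraries).

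**Figure D5:**
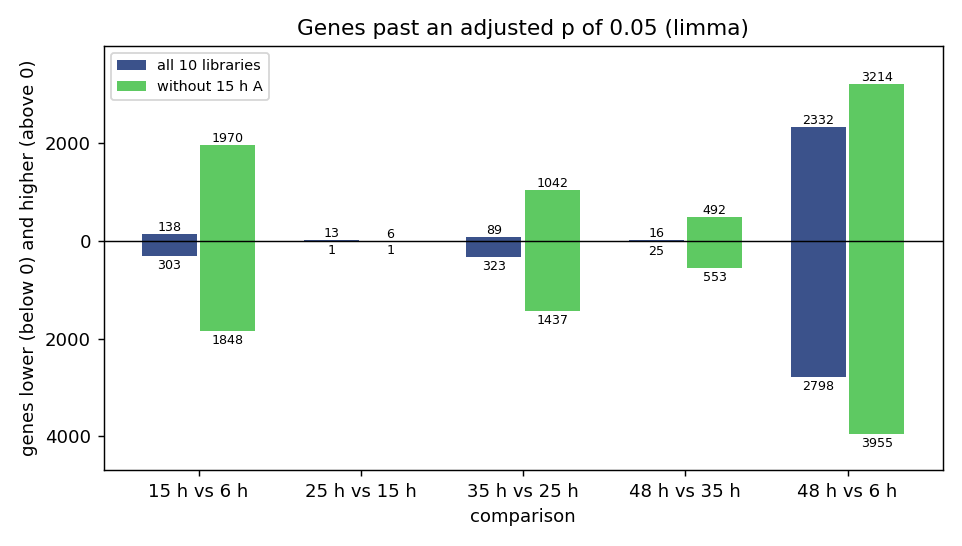
Bars give the number of genes higher and lower past an adjusted p of 0.05 (limma) in each comparison. They are drawn for all 10 libraries and without 15 h A, and start at 0. Leaving out 15 h B in place of 15 h A, which is not drawn, gave more calls than all 10 libraries in every comparison. The counts for 15 h against 6 h are 138 and 303 with all libraries and 1970 and 1848 without 15 h A.

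Over all 5 times 4014 genes (38.4%) passed the F test. The highest mean was at 6 h for 1666 of them, at 15 h for 335, at 25 h for 351, at 35 h for 595 and at 48 h for 1067. A middle time was above both 6 h and 48 h for 59 genes, 51 of them at 25 h, 6 at 15 h and 2 at 35 h, and below both for 21 genes. The 5 largest peaks under the naming rule, all at 25 h, were the fat body genes Lsp2, Lsp1alpha, Lsp1gamma and Fbp2 and the odorant-binding gene Obp99b. They lay above each end by at least 6.16, 5.79, 4.71, 4.65 and 5.16 on the log2 scale. The 5 largest dips were Vajk4 (35 h), hll, an acyl-CoA synthetase gene, and Obp56d, an odorant-binding gene (15 h), mthl3 (35 h) and Ugt36D1, a glycosyltransferase gene (15 h). The last 4 lay below each end by at least 2.40, 2.25, 1.78 and 1.30, and Vajk4 had only 1 or 2 reads per library at 35 h. The F test count was 1609 to 7906 and the peak and dip counts 14 to 1619 and 0 to 618 with 1 library left out, so these counts depend on single libraries.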

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

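The alternative that leaves out 15 h A and 25 h A together was chosen only after the results were seen; every other alternative here was chosen beforehand. Where 1 library of a time is left out, the lone remaining library is assumed to vary like the others. Counts are given as higher and lower genes past an adjusted p of 0.05. Where no cause is named below, the cause was not tested.

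The calls at 48 h against 6 h depended on single libraries of these 2 times: of 5130, 2953 were shared without 6 h A, 2919 without 6 h B, 2677 without 48 h A and 2487 without 48 h B, against 4291 to 5130 without 1 library of another time. Their balance depended on the scaling: 45.5% were rises as deposited, 66.5% after quantile normalization and 58.8% with a common median. The counts of 2332 and 2798 stayed within 1.5 times under every alternative except quantile normalization (3538 and 1783) and some fits with 1 library left out, and of the 5130 genes 5072 were called in the same direction from the 4 libraries of the 2 times alone, 5052 by DESeq2, 4876 with the block, 4724 by edgeR, 4498 with a common median and 3812 after quantile normalization. The counts between neighbouring times were not stable.

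A pseudocount of 5 gave 3 lower genes at 25 h against 15 h, no filter gave 8 higher there and 50 higher at 35 h against 25 h, and a filter of at least 50, which tested fewer genes, gave 4 higher at 25 h against 15 h. Quantile normalization gave 9 and 14 at 15 h against 6 h, 8 and 0 at 25 h against 15 h (730 and 668 at an unadjusted p under 0.05), 18 and 115 at 35 h against 25 h, and 0 and 1 at 48 h against 35 h (342 and 377 unadjusted). It also gave 980 genes with the highest mean at 6 h and 214 at 15 h, and 35 genes higher and 4 lower at a middle time. A shift to a common median gave 4 and 5 at 15 h against 6 h, 45 higher at 35 h against 25 h, 8 and 13 at 48 h against 35 h, and 7 lower at a middle time. These 2 scalings differ from the deposited one by construction in the median of each library.

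The fit of the 2 times alone has fewer libraries to estimate the spread, and at steps without 15 h it leaves out the 15 h pair. It gave 0 and 0 at 15 h against 6 h (179 and 885 unadjusted) and 0 and 0 at 25 h against 15 h (289 and 192 unadjusted). At 35 h against 25 h it gave 356 higher, and at 48 h against 35 h 624 and 496. These larger counts go with narrower pairs: the SD of the log2 difference between replicates was 1.66 at 15 h, 0.872 at 25 h, 0.646 at 35 h and 0.537 at 48 h. With the replicate letter as a block the counts were 72 higher at 15 h against 6 h, 4 and 0 at 25 h against 15 h (736 and 861 unadjusted), 47 and 193 at 35 h against 25 h, 0 and 2 at 48 h against 35 h (559 and 688 unadjusted), and 10 lower at a middle time. Differences between A and B correlated over 0.1 across genes for only 2 of the 10 pairs of times (-0.06 to 0.16). That gives little sign that the letters pair libraries, but it cannot exclude a shared culture or batch.

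edgeR gave 0 and 0 at 15 h against 6 h (1029 and 1130 unadjusted), 2 higher at 25 h against 15 h, 21 and 130 at 35 h against 25 h, 5 and 5 at 48 h against 35 h, and 35 higher and 6 lower at a middle time. DESeq2 gave 666 and 715, 383 and 785, 406 and 840, and 247 and 322 at the 4 steps in order. For DESeq2 the F test count was replaced by a likelihood ratio count of 6114, with 906 highest at 15 h and 921 at 35 h, and 212 higher and 116 lower at a middle time. In simulated data at 48 h against 6 h, 37.2% of the DESeq2 calls were false. That share depends on how many genes change, and few were changed in the simulation. It is therefore not an estimate of the false share among the DESeq2 counts given here.

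With 1 library left out, the ranges were 0 to 1975 and 0 to 1848 at 15 h against 6 h, 0 to 2185 and 0 to 2721 at 25 h against 15 h, 0 to 1042 and 0 to 1437 at 35 h against 25 h, 0 to 492 and 0 to 553 at 48 h against 35 h, and 1115 to 3214 and 1384 to 3955 at 48 h against 6 h (limma; the report gives unadjusted counts and those of edgeR and DESeq2 where no gene passed either way). The F test ranged from 1609 to 7906. Genes with the highest mean at 6, 15, 25, 35 and 48 h numbered 595 to 3136, 62 to 2800, 174 to 574, 185 to 1291 and 463 to 1719, and those higher or lower at a middle time 14 to 1619 and 0 to 618. The highest counts came from leaving out 15 h A or 15 h B, which also removes the widest gap between replicates from the spread. With 15 h A and 25 h A both left out the counts at the 4 steps were 2064 and 2328, 32 and 8, 505 and 956, and 649 and 703. The F test then gave 7139, with 3404, 522, 1080 and 1696 highest at 6, 15, 35 and 48 h, and 399 higher and 307 lower at a middle time.

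Of 325 pairs of a named gene and a comparison, 230 were called. A pair counted as reversed when its sign changed and it was called in at least 1 of the 2 fits. No pair reversed under a change of pseudocount, filter, scaling, spread estimate or tool. Pairs that changed sign with no call in either fit numbered 10 after quantile normalization and 6 with a common median. There were 5 in edgeR, 2 in DESeq2 and 1 with a pseudocount of 5. The pairs that fell short of the threshold numbered 4 with either pseudocount, 17 with no filter, 6 with a filter of at least 50 (24 were not tested), 96 after quantile normalization, 62 with a common median, 60 in the 2 times alone, 48 with the block, 79 in edgeR and 5 in DESeq2. With 1 library other than those of 15 h left out, 63 to 132 fell short. Leaving out 15 h A or 15 h B removes the gap between these libraries from the spread shared by all times. In either fit more pairs newly passed than fell short. Changes between other times kept their log2 values there, so these passes do not single out 15 h A. Those that reversed were chinmo at 15 h against 6 h without 15 h A (0.31, left-out range -0.31 to 0.31, adjusted p 0.0326 to 1 over its alternatives; 0.31 without both), ap at 15 h against 6 h without 15 h B (-0.35, left-out range -0.35 to 0.40, adjusted p 0.00599 to 0.987), ab at 25 h against 15 h without 15 h B (0.29, left-out range -0.46 to 0.29, adjusted p 0.0487 to 0.979) and dpp at 15 h against 6 h with 15 h A and 25 h A both left out (0.35, left-out range -0.49 to 0.35, adjusted p 0.0145 to 0.998). None of these 4 was called with all 10 libraries.

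Of 63 set tests past the threshold with the preset correlation, 63 kept their call under each pseudocount and the block, 61 with no filter, 54 with a filter of at least 50, 49 after quantile normalization, 53 with a common median, 58 in the 2 times alone, 59 in edgeR, 53 in DESeq2 and 47 to 61 with 1 library left out. Ribosomal proteins reversed under the scalings, with adjusted p 0.577 at 35 h against 25 h (range 9.14e-15 to 0.577) and 0.907 at 48 h against 6 h after quantile normalization, and 0.654 at 48 h against 6 h with a common median (range 1.97e-05 to 0.907). At 25 h against 15 h without 15 h A, E(spl) genes reversed (0.872; left-out range 0.00171 to 0.872), as did Hippo genes (0.214; 0.000275 to 0.214), G1 to S phase genes (5.41e-05; 3.15e-09 to 0.0896) and G2 to M phase genes (8.90e-05; 5.91e-10 to 0.0478). With 15 h A and 25 h A both left out these 4 lists reversed at 0.731, 0.262, 0.00438 and 0.00346. At 15 h against 6 h without 15 h B, Hippo genes reversed (0.652; 2.84e-05 to 0.652), as did G2 to M phase genes (0.00267; 1.08e-11 to 0.0468, and up to 0.370 over all alternatives).

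Depth limited the low end of the range, where 1 read equalled a signal of 0.596 to 1.40. In simulated data limma called 2% to 6% of genes changed 2-fold and 26% to 52% of genes changed 4-fold, so a gene that did not pass is not shown to be unchanged.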

Other observations

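The Jonah protease test, the test of 15 h A against libraries of other times and the test of storage proteins against apolpp were chosen only after the result was seen, as were the lists of trypsins, maltases, lysozymes, Jonah proteases, midgut regulators and lipid enzymes.

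The libraries of 48 h differed in the genes below, which, like AkhR in the next paragraph, were singled out after their values were seen. Hr4 was at 2910 in 48 h A and 300 in 48 h B, Blimp-1 at 3474 and 671, Spn100A at 3483 and 829, and the matrix protease gene Mmp1 at 4054 and 1267. Hr3, a nuclear receptor gene under the filter, was at 45.5 and 0.6.

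Other values stood in single steps. AkhR, the receptor gene for adipokinetic hormone, peaked at 25 h (442, above each end by at least 1.86 on the log2 scale), and Jra, which encodes Jun, peaked at 15 h (1597, by at least 0.53). RpL23A dipped at 35 h (20761, by at least 0.91 below each end).

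Library 15 h A stood apart from 15 h B. Its median difference from 15 h B was 6.32 for maltases (7 of 8 higher), 5.88 for lysozymes (5 of 6) and 5.51 for trypsins (10 of 10), and lysozymes took 1.47% of its reads, trypsins 0.994%, maltases 0.422% and midgut regulators 0.0230%; epsilonTry was at 161638 in 15 h A. The 6 midgut regulators outside these families were higher by a median of 4.05 (6 of 6, spread 0.982), in a test that could have come out otherwise, which is consistent with a piece of gut in that library. Jonah proteases did not rise as a set (median -0.0920, 8 of 16 higher, spread 3.42), which argues against a midgut that brings them all as the trypsins were brought (5.51); but their share was 0.692% in 15 h A and 0.0675% in 15 h B, with Jon25Bi at 118004 and 4939, so a part of the midgut stays open. The tables argue against 15 h A being a library of another sampled time with no added tissue. Its highest Spearman correlation with another time was 0.928 (6 h A), while replicates of the other times reached 0.976 to 0.994. A library of another time with gut in it stays open. A library of an age that was not sampled also stays open, since this test cannot address it.

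Fat body genes were highest at 25 h, where Lsp1gamma had 1223710 ± 852047 and Lsp1alpha 729897 ± 200767, and the list was higher in 25 h A than in 25 h B by a median of 1.40 (7 of 9). Lipid and fat body enzymes outside the fixed list were higher in 25 h A than in 25 h B by a median of 0.976 (12 of 13; 0.588% and 0.374% of the reads), smaller than the spread of 1.10 among them. This goes with more fat body in 25 h A than in 25 h B, but the same enzymes took 0.546% and 0.739% of the reads at 6 h, and their median level relative to the mean of the 10 libraries was 0.77 and 1.12 at 6 h and 1.23 and 0.19 at 25 h. Whether fat body tissue explains the peak at 25 h stays open. A larger share of unchanged fat body alone is argued against by the ratio of Lsp1 genes to apolpp, which was -0.707 and -0.848 on the log2 scale at 6 h and 2.66 and 3.17 at 25 h, a difference of 3.70. This holds against 6 h: the ratio was 1.66 and 2.51 in 15 h A and B, 3.19 and 3.42 at 35 h and 3.55 and 3.45 at 48 h, so a change of share stays open for the fall after 25 h. A change of the fat body with age, beside a change of its share, stays open and was not tested.

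The lists that fell after 6 h were read against other tissue in the early libraries. For gut in the 6 h libraries, ribosome biogenesis genes were lower in 15 h A than in 15 h B by a median of -0.546 (0 of 24 higher, spread 0.141), below the bound of 0 set beforehand. That bound was wrong, because it rests on 1 library and wing axis genes were lower there by -0.65 as well, so gut and other tissues stay open for this list. For the respiratory chain, the median change from 15 h B to 48 h was -0.768 (5 of 71 higher, spread 0.248), below the bound of -0.5 set beforehand. This bound was wrong too, because 15 h B still held muscle genes 4.80 above their 48 h level on the log2 scale, and muscle is rich in respiratory chain transcripts. Respiratory chain genes were higher in 15 h A than in 15 h B by a median of 1.26 (67 of 71 higher). They were also higher in 25 h A than in 25 h B, by 0.488 (67 of 71). These are the libraries in which gut or fat body genes were higher. For this list a fall in the disc and a loss of other tissue cannot be told apart. The share of other tissue bears on lists that rose as well, such as the wing axis genes, and was not tested for them.

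The tests above concern other tissue and a library of another sampled time. Time is the only group of the design, so no biological explanation was tested, and the age of the larvae stays open for the 2 patterns across times; 15 h A and 15 h B have the same stated time.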
